A study of Homo sapiens with 6 samples.

How the data were processed

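RNA from 6 samples of T47D-YA cells was sequenced, 2 per group: empty vector, 18 kDa FGF2 and 22.5 kDa FGF2. Per the labels' protocols, total RNA was extracted with TriReagent, and directional paired-end libraries were made with a TruSeq kit and read on an Illumina instrument. The values are counts of reads per Entrez gene as the authors deposited them, whole numbers with no normalization. Genes with no read in any library (5136 of 23459) are in the table, so no low-count filter had been applied. Per the submitters' processing notes the genome build was hg19 and edgeR was used. The aligner, the counter and its strand setting are not given in the sources used here. The counted totals, 5317687 to 6817324, are far below the number of reads per sample that the labels' protocols give, and the reason is not given in the sources used here. Gene symbols came from a RefSeq table of another assembly (GRCh38), matched on the Entrez ID for 23308 genes and used only for names, neighbours and the chromosome a gene lies on, so no coordinates are given. Transcript length and GC content, medians over the transcripts of a gene, came from GENCODE release 29 and were found for 12902 of 13124 tested genes (98.3%).

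Groups were taken from the labels, and no sample was left out. The labels number the samples of a group but do not say whether they came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No replicate pair held identical values, and each differed by more than counting noise in a chi-square test over genes with a pair count of at least 20.

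Counts were fitted in R 4.3.3 with edgeR 4.0.16 (TMM factors, filterByExpr by group, trended dispersion, robust quasi-likelihood fit). All 6 libraries entered 1 model, so that the groups share 1 estimate of the spread on 3 residual degrees of freedom. The filter kept 13124 genes and removed 10335, and the common biological coefficient of variation was 0.199. Each comparison was tested two-sided with glmQLFTest and Benjamini-Hochberg adjustment over the genes tested, and passing means an adjusted p under 0.05. Every adjusted p of a gene is from this test unless another is named. Levels are TMM-scaled CPM, mean ± SD over 2 libraries. An exact permutation test of 2 libraries against 2 cannot go below p = 0.333, so none was used. A gene with no count in a group has its fold stated as a lower bound, against a floor of 3 counts per library. A gene with 1 to 3 counts has the ratio of counts with an exact binomial 95% interval. Intervals and floors cover counting error only.

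Gene lists were tested two-sided with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 23 lists with at least 5 measured members. They were tested again with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way and does not compare them with other genes. With camera 5 lists passed for 18 kDa FGF2, 8 for 22.5 kDa FGF2 and 0 between the isoforms, and with fry 7, 7 and 0. With the estimated correlation 0 passed in each comparison (1, 2 and 0 at an unadjusted p under 0.05). That setting takes its p-values from the 3 residual degrees of freedom, which raises them. A call lost there is thus not by itself a sign of correlated genes. The list of mitochondrially encoded genes, a sign of RNA quality, had 0 measured members and was not analysed here.

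The tests, the lists and the rule for named genes were fixed before the data were examined. Per comparison the rule takes the 10 genes with the highest and the 10 with the lowest log2 fold change among those that passed with an average log2 CPM of at least 1 and no overlap of the groups' CPM. It passes over symbols of uncharacterised genes, XIST and Y-linked genes. It always takes FGF2, NUDT6, FGFR1 to FGFR4, PGR, ESR1 and CTNNB1. From each list it takes up to 4 members that passed, by smallest p, and where fewer than 2 passed also the 2 measured members with the highest mean CPM. Not every gene it takes is printed, and some results are not reported here.

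The test was checked on counts simulated from the real means and library sizes, with known genes changed by known folds. For 18 kDa FGF2 against the empty vector (12902 genes) it recovered 38 of 99 genes changed 2-fold (38.4%) and 89 of 98 changed 4-fold (90.8%), with 7 false calls (5.22% of calls). For 22.5 kDa FGF2 against the empty vector (12916 genes) it recovered 31 of 100 changed 2-fold and 82 of 100 changed 4-fold, with 6 false calls (5.04%). For 22.5 kDa against 18 kDa FGF2 (12901 genes) it recovered 42 of 99 changed 2-fold (42.4%) and 82 of 98 changed 4-fold (83.7%), with 11 false calls (8.15%). A raised list was called in each comparison and 0 of 20 unchanged lists were. The simulated genes were drawn independently of each other, so this does not show how the list test behaves with correlated genes. This check was written after the real counts had first been fitted.

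Alternatives fixed before the data were examined were RLE and upper-quartile size factors, no low-count filter, a filter of at least 1 CPM in at least 2 libraries, DESeq2 1.42.0, limma-voom, edgeR's likelihood ratio test, the replicate number as a block, only the groups compared, glmTreat against a fold of 1.5, and leaving out each library in turn. Where that leaves 1 library in a group, it is assumed to vary like the other groups. Leaving out both replicate 1 libraries of the FGF2 groups, a crossed block and removal of each library's GC trend were chosen after seeing the data. Unchanged groups against the shared controls were simulated 20 times.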

Results

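RNA sequencing measured mRNA in T47D-YA cells, a derivative of the luminal breast cancer line T47D that expresses the A form of the progesterone receptor. There were 3 groups of 2 libraries each: cells with an empty vector, cells overexpressing the 18 kDa isoform of fibroblast growth factor 2 (FGF2), and cells overexpressing its 22.5 kDa isoform. The 18 kDa isoform is the form that cells export, and the larger isoforms start at upstream codons and reside mainly in the nucleus. The series names nuclear FGF2 and Wnt signalling in resistance to antiprogestins, so each comparison with the empty vector asks which of these genes changed with an isoform. The counted totals were 5317687 and 5413904 for the empty vector, 6817324 and 5670206 for 18 kDa FGF2, and 6136593 and 5345384 for 22.5 kDa FGF2. Of 23459 genes in the table, 13124 had enough counts to be tested.

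FGF2 (Entrez 2247), the overexpressed gene, had 12 and 13 counts in the empty vector libraries, 6259 and 4365 in the 18 kDa libraries, and 8731 and 7758 in the 22.5 kDa libraries. Its level was 2.29 ± 0.208 CPM in the empty vector, 864 ± 137 CPM with 18 kDa FGF2 and 1444 ± 157 CPM with 22.5 kDa FGF2 (SD, n = 2 each). Against the empty vector the log2 fold changes were 8.55 (SE 0.36, adjusted p = 1.18e-14) and 9.29 (SE 0.36, adjusted p = 2.48e-15). Between the isoform groups FGF2 differed by 0.74 on the log2 scale (SE 0.23), which did not pass the test (adjusted p = 0.118). Counts per gene do not tell the isoforms apart, nor the introduced gene from the cell's own. NUDT6, the antisense neighbour of FGF2, did not pass in either comparison with the empty vector (log2 fold change -1.30, SE 0.59, adjusted p = 0.208 with 18 kDa and -1.93, SE 0.64, adjusted p = 0.0531 with 22.5 kDa FGF2). The strand setting of the counting is not given in the sources used here, so the NUDT6 values are uncertain.

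The first principal component held 48.6% of the variance and parted both FGF2 groups, at 21.3 to 32.6, from the empty vector, at -53.2 and -51.2. Along the second, which held 25.5%, the 18 kDa libraries lay at -48.0 and -2.65 and the 22.5 kDa libraries at 42.7 and 8.29, so replicates of 1 group lay far apart. Replicates of a group differed by more than counting noise, with a chi-square per degree of freedom of 6.20 in the empty vector, 14.3 with 18 kDa FGF2 and 14.2 with 22.5 kDa FGF2.

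**Figure D1:**
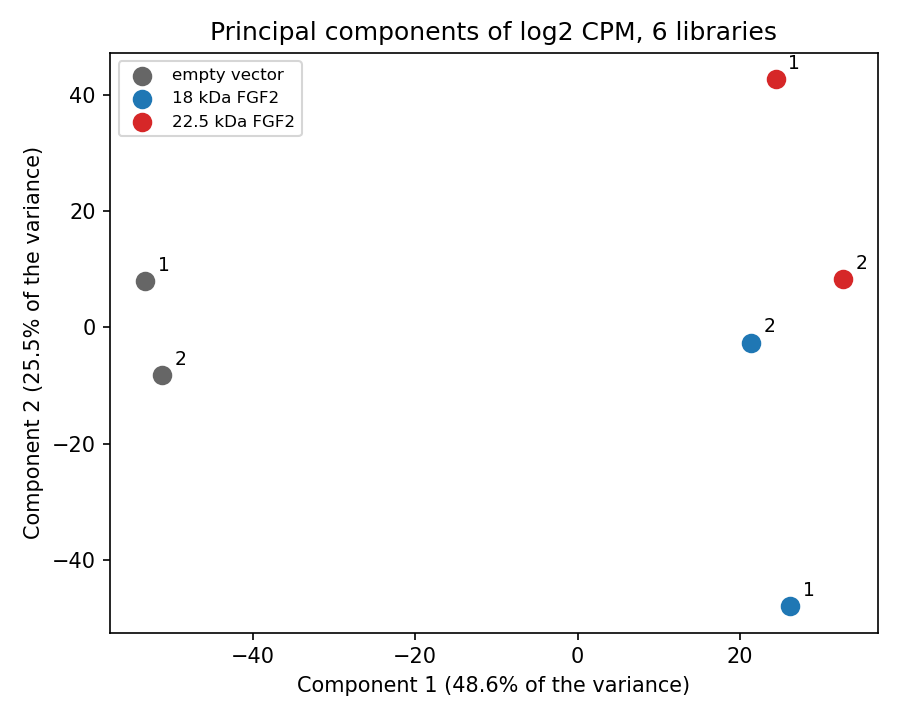
Principal components of log2 CPM over the genes tested, with component 1 (48.6% of the variance) on the horizontal axis and component 2 (25.5%) on the vertical axis, both in arbitrary units, and 1 point for each of the 6 libraries. The empty vector libraries lie at -53.2 and -51.2 on component 1, and the FGF2 libraries at 21.3 to 32.6.

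With 18 kDa FGF2, the mRNAs of the estrogen and progesterone receptors fell. PGR (Entrez 5241), the progesterone receptor gene, went from 215 ± 18.6 to 22.9 ± 12.4 CPM (SD, n = 2), 9.45-fold lower (log2 fold change -3.24, SE 0.31, adjusted p = 9.78e-06). Counts per gene would not tell an introduced copy of PGR from the cell's own gene. ESR1 (Entrez 2099), the gene of estrogen receptor alpha, went from 14 ± 1.38 to 1.20 ± 1.04 CPM (log2 fold change -3.57, SE 0.53, adjusted p = 4.63e-05). FGFR1, an FGF receptor, fell by 1.47 on the log2 scale (SE 0.27, adjusted p = 0.000506). The receptors FGFR3 (-1.24, SE 0.29, adjusted p = 0.00609) and FGFR4 (-0.99, SE 0.29, adjusted p = 0.0321) passed as well. FGFR3 missed the threshold without empty vector replicate 1 (0.0591) or 2 (0.062), and FGFR4 without empty vector replicate 1 (0.256) or 2 (0.149) or 18 kDa replicate 1 (0.0893) or 2 (0.0717), with adjusted p-values of 2.07e-05 to 0.0887 and 0.000664 to 0.342 over their alternatives. FGFR2 (-1.28, SE 0.53, adjusted p = 0.16) and CTNNB1, the gene of beta-catenin (-0.11, SE 0.26, adjusted p = 0.866), did not pass.

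**Figure D2:**
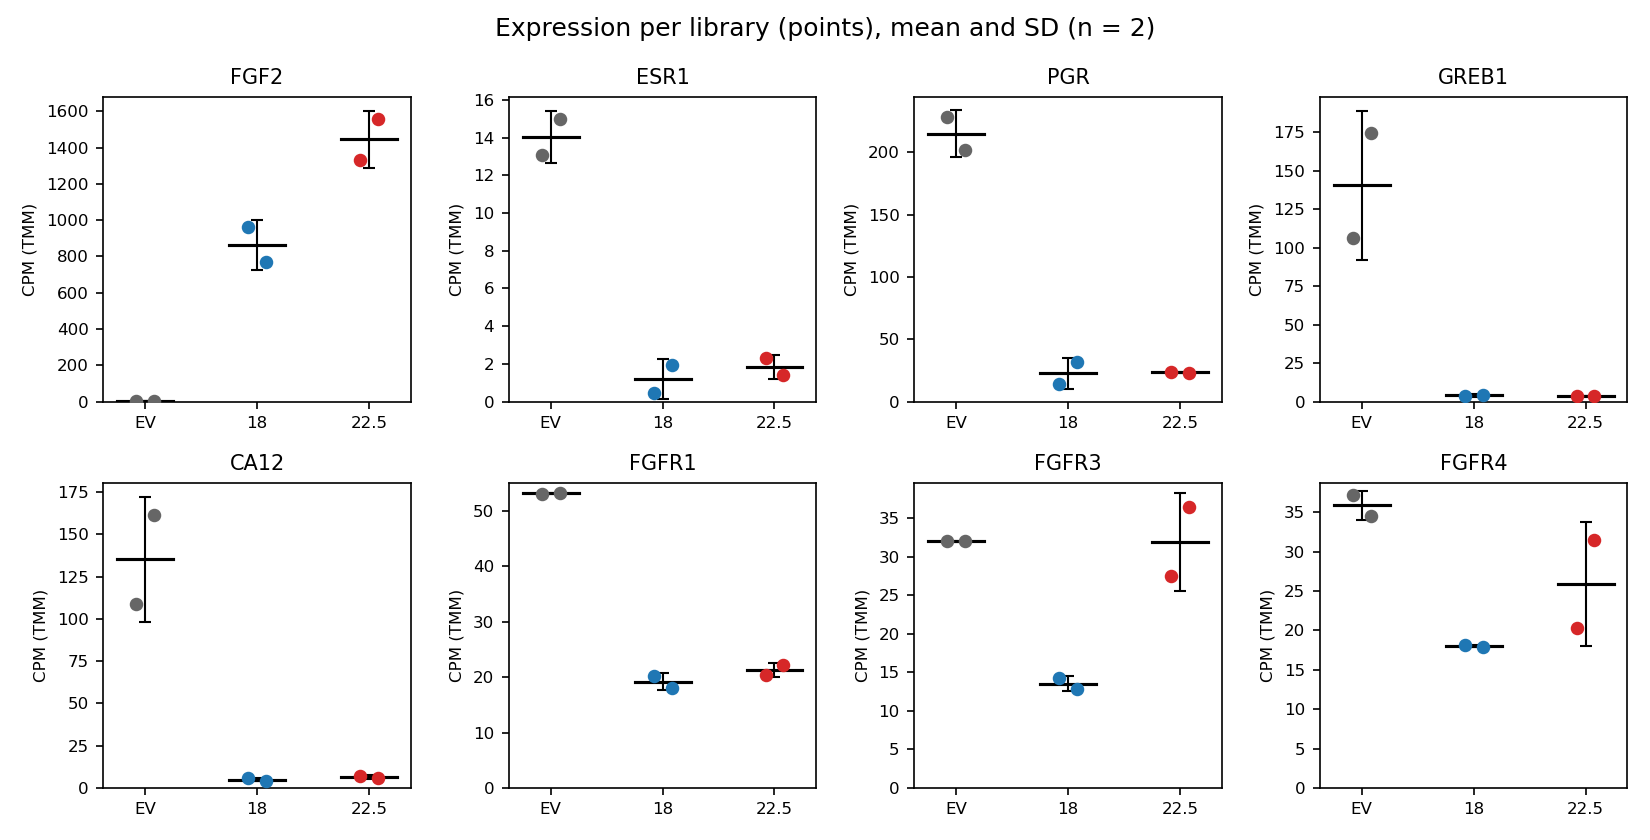
TMM-scaled CPM on linear axes for 8 genes in the empty vector, 18 kDa FGF2 and 22.5 kDa FGF2 groups, where points are libraries and bars show the mean and SD (n = 2). PGR was at 215 CPM in the empty vector and at 22.9 and 23.6 CPM with the isoforms.

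Estrogen-regulated genes had the lowest camera p of the lists with 18 kDa FGF2. Of 26 measured members, 14 fell and 2 rose (14 and 3 adjusted over the list alone). GREB1, an estrogen receptor target and cofactor, went from 141 ± 48.4 to 4.05 ± 0.734 CPM (log2 fold change -5.12, SE 0.32, adjusted p = 4.01e-11). The carbonic anhydrase gene CA12 fell by 4.76 and the transcription factor gene XBP1 fell by 1.73 on the log2 scale, while the receptor tyrosine kinase gene RET rose by 2.42. The camera test gave the list adjusted p = 1.11e-06, and adjusted p = 0.602 with an estimated correlation.

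Of 20 FGF-ERK feedback and early response genes, 7 fell and 0 rose with 18 kDa FGF2 (9 and 0 adjusted over the list alone). DUSP4, a phosphatase of ERK, fell by 3.76 and PHLDA1 fell by 2.19 on the log2 scale. The transcription factor gene EGR3, which the estrogen list also holds, was at 26.0 ± 10.2 CPM in the empty vector and had no count with either isoform, so that it was at least 52.6-fold lower with 18 kDa FGF2. The list had camera adjusted p = 0.00134, and adjusted p = 0.602 with an estimated correlation. It missed the threshold without 18 kDa replicate 2 (0.0602), and its adjusted p ranged over 3.83e-05 to 0.602 across its alternatives.

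Interferon, cholesterol and fibroblast lists also passed downward with 18 kDa FGF2 in the camera test. Of 29 interferon response genes, 3 fell and 0 rose (6 and 0 adjusted over the list alone), among them HERC6, an interferon-induced ubiquitin ligase gene, which fell by 2.62. Its camera adjusted p was 0.00178, with adjusted p = 0.728 with an estimated correlation, and it missed the threshold without empty vector replicate 1 (0.201). Of 27 cholesterol and fatty acid synthesis genes, 2 fell and 0 rose (2 and 0 adjusted over the list alone). The lanosterol synthase gene LSS fell by 0.88 but missed the threshold without empty vector replicate 2 (0.267) or 18 kDa replicate 2 (0.138) (4.21e-06 to 0.373 over its alternatives). That list had camera adjusted p = 0.00964, adjusted p = 0.602 with an estimated correlation, and missed the threshold without 18 kDa replicate 2 (0.236). Of 5 fibroblast markers, 1 fell and 0 rose (1 and 0 adjusted over the list alone), the surface glycoprotein gene THY1 (-3.23). That list had camera adjusted p = 0.0432, adjusted p = 0.602 with an estimated correlation, and missed the threshold without empty vector replicate 1 (0.201), 18 kDa replicate 1 (0.206) or 2 (0.0602) or 22.5 kDa replicate 1 (0.0834) or 2 (0.0592). Across their alternatives the adjusted p-values of these lists ranged over 5.53e-08 to 0.728, 0.00135 to 0.602 and 0.00354 to 0.602.

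Neither Wnt list passed with 18 kDa FGF2, and single members moved both ways. Of 15 Wnt/beta-catenin target genes, 1 rose and 3 fell (3 and 4 adjusted over the list alone, camera adjusted p = 0.624). RNF43, a negative regulator of Wnt receptors, rose by 1.36 and SOX9, a transcription factor gene, fell by 3.46. LEF1, a transcription factor of the pathway, had 73 counts in the empty vector and 0 with 18 kDa FGF2 (at least 13.6-fold lower). KREMEN1 fell by 1.10 but missed the threshold without empty vector replicate 2 (0.0624) or 18 kDa replicate 2 (0.0815) (2.45e-06 to 0.121 over its alternatives). Of 27 Wnt ligands, receptors and modulators, 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.885). The ligand gene WNT4 rose by 2.40, and WLS, which carries Wnt ligands to the cell surface, went from 20.4 ± 1.77 to 0.318 ± 0.201 CPM (log2 fold change -5.87, SE 0.57, adjusted p = 1.26e-07). PORCN rose by 1.19 and ROR2 rose by 1.07, but PORCN missed the threshold without empty vector replicate 1 (0.0884) or 2 (0.154) and ROR2 without empty vector replicate 1 (0.073) (7e-05 to 0.154 and 1.21e-05 to 0.099 over their alternatives).

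Androgen-regulated and lineage lists did not pass with 18 kDa FGF2 in the camera test, and single members moved both ways. Of 16 androgen-regulated genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.624). With fry this list passed downward (adjusted p = 0.00594, 0.00594 to 0.78 over its alternatives). AZGP1, a secreted glycoprotein gene, fell by 3.79 and the receptor co-chaperone gene FKBP5 fell by 1.46, while GGT1 rose by 1.20 and PMEPA1 rose by 0.99. GGT1 missed the threshold without empty vector replicate 2 (0.0547), and PMEPA1 without empty vector replicate 1 (0.0961) or 2 (0.0633) or 18 kDa replicate 1 (0.268) (1.52e-06 to 0.0547 and 9.01e-05 to 0.268 over their alternatives). Of 19 progestin-regulated genes, 2 rose and 5 fell (3 and 8 adjusted over the list alone, camera adjusted p = 0.624), with the endothelin gene EDN1 at 2.40 and the alveolar transcription factor gene ELF5 at -1.69. Of 13 basal genes, 4 rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 0.624), with TRIM29 at 2.91 and the laminin genes LAMB3 at 1.99 and LAMA3 at -3.96. Apocrine genes had 4 and 2 of 13 higher and lower (4 and 2 adjusted over the list alone, camera adjusted p = 0.624) and luminal genes 1 and 3 of 21 (3 and 5 adjusted over the list alone, 0.885).

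The other lists did not pass with 18 kDa FGF2 in the camera test. With fry, FGF ligands and receptors (adjusted p = 0.0291, 0.0233 to 0.676 over its alternatives) and epithelial-mesenchymal transition genes (0.00425, 0.00425 to 0.602) passed downward, and interferon genes did not pass (0.236, 5.53e-08 to 0.728). Members higher and lower, with the counts adjusted over the list alone and the camera adjusted p in brackets, were 1 and 6 of 15 FGF ligands, receptors and co-receptors (1 and 8, 0.0796), 2 and 3 of 38 cell cycle genes (2 and 4, 0.283), 0 and 3 of 10 epithelial-mesenchymal transition genes (0 and 4, 0.0796) and 2 and 3 of 13 stem and progenitor genes (2 and 3, 0.356). They were 2 and 2 of 25 unfolded protein response genes (2 and 2, 0.553), 1 and 3 of 24 hypoxia and glycolysis genes (1 and 3, 0.812), 2 and 0 of 27 nucleolar genes (3 and 0, 0.0796), 2 and 0 of 23 apoptosis regulators (2 and 3, 0.624) and 2 and 2 of 18 growth factors and chemokines (2 and 2, 0.624). The syndecan gene SDC1 rose by 1.56, SDC2 fell by 3.76, and the matrix genes FN1 and THBS1 were at -2.42 and -4.00. Heat shock genes had 0 and 0 of 15 members (0 and 0, 0.624) and histone genes 0 and 0 of 9 members (0 and 0, 0.636) with edgeR. Of 3 endothelial, 1 leukocyte and 4 adipocyte markers measured, too few for a list test, 1 endothelial marker rose and 1 fell, and 2 adipocyte markers fell, PLIN4 (-1.70) and LPL (at least 4.07-fold lower). Adjusted over the list alone these were 1 and 2, 0 and 0 and 1 and 2 higher and lower. Median, mean and test differed in sign for the apocrine, luminal, basal and hypoxia lists.

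Across all genes, 1165 of 13124 passed with 18 kDa FGF2, 537 higher and 628 lower, 332 and 526 of them by over 2-fold. GRIK4, a kainate receptor gene, had no count in the empty vector and was at least 18.4-fold higher. The chemokine gene CCL2 rose by 7.19 (SE 0.48), the adhesion gene DSCAM rose by 5.74 (SE 0.43) and keratin KRT10 rose by 4.03 (SE 0.26, 1629 ± 34.1 against 99.8 ± 10.1 CPM). SSX2 and SSX2B held identical counts in every library, 87.1-fold higher (interval 29.5 to 425), and as near-identical copies their values are uncertain. NTN4 was 40.3-fold higher (interval 10.8 to 338). Among the lowest, ZDHHC4, a palmitoyltransferase gene, had 402 counts in the empty vector and 0 with 18 kDa FGF2 (at least 74.6-fold lower). PSORS1C2 was 202-fold lower (interval 68.6 to 980), RHAG 173-fold (30.6 to 6890) and the transcription factor gene TFAP2B 72.6-fold (19.7 to 606). PORCN, SSX2 and SSX2B on chromosome X lie in windows of 25 neighbouring tested genes with median log2 fold changes of 0.75 to 0.99, SDC1 on chromosome 2 in windows of 0.65 to 0.67 and ZDHHC4 on chromosome 7 in windows of -0.68 to -0.63, beyond what permuted gene orders gave. The count was 617 without empty vector replicate 1, 665 without replicate 2, and 496 against a fold of 1.5, where 33.9% were higher against 46.1%. It was 1915 without both replicate 1 libraries of the FGF2 groups and 1813 after removal of each library's GC trend. More genes were higher than lower with DESeq2 (50.6%), without 22.5 kDa replicate 2 (51.8%) and without both replicate 1 libraries (50.1%). Of 90 named genes that passed, 59 still passed without any 1 of the 6 libraries.

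With 22.5 kDa FGF2, PGR, ESR1 and FGFR1 fell against the empty vector. PGR was at 23.6 ± 0.511 CPM, 9.09-fold lower (log2 fold change -3.18, SE 0.31, adjusted p = 8.77e-06). ESR1 was at 1.85 ± 0.628 CPM (log2 fold change -2.88, SE 0.50, adjusted p = 0.000245), and it missed the threshold without 22.5 kDa replicate 2 (0.0523) (1.59e-11 to 0.0523 over its alternatives). FGFR1 fell by 1.32 (SE 0.27, adjusted p = 0.00127). FGFR2 (-0.88, SE 0.52, adjusted p = 0.319), FGFR3 (-0.01, SE 0.28, adjusted p = 0.996), FGFR4 (-0.48, SE 0.29, adjusted p = 0.345) and CTNNB1 (0.18, SE 0.26, adjusted p = 0.75) did not pass.

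Of 26 estrogen-regulated genes, 13 fell and 3 rose with 22.5 kDa FGF2 (15 and 3 adjusted over the list alone). GREB1 fell by 5.20 on the log2 scale and CA12 fell by 4.39, and RET rose by 2.90. Camera adjusted p was 1.48e-07, and adjusted p = 0.489 with an estimated correlation. Of 20 FGF-ERK feedback genes, 7 fell and 0 rose (10 and 0 adjusted over the list alone), with DUSP4 at -3.33 and EGR3 at least 49.1-fold lower. That list had camera adjusted p = 3.13e-05, and adjusted p = 0.489 with an estimated correlation. Of 15 FGF ligands, receptors and co-receptors, 4 fell and 0 rose (4 and 0 adjusted over the list alone), with the heparan sulfate proteoglycan gene SDC2 at -4.80 and FGFR1 at -1.32. Camera adjusted p was 0.0122, adjusted p = 0.489 with an estimated correlation, and the list missed the threshold without empty vector replicate 2 (0.0717) or 22.5 kDa replicate 1 (0.144) (0.0094 to 0.489 over its alternatives).

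Of 10 epithelial-mesenchymal transition genes, 4 fell and 0 rose with 22.5 kDa FGF2 (4 and 0 adjusted over the list alone). The cytokine gene TGFB1 fell by 3.86, fibronectin FN1 fell by 2.20, thrombospondin THBS1 fell by 3.14 and the receptor kinase gene AXL fell by 2.30. THBS1 missed the threshold without 22.5 kDa replicate 2 (0.0522), and AXL without empty vector replicate 1 (0.343) or 22.5 kDa replicate 1 (0.212) or 2 (0.159) (4.42e-10 to 0.0522 and 0.00316 to 0.343 over their alternatives). The list had camera adjusted p = 0.00675, and adjusted p = 0.489 with an estimated correlation. Of 27 cholesterol and fatty acid synthesis genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone). INSIG1, a regulator of sterol synthesis, fell by 0.79 but missed the threshold without empty vector replicate 1 (0.0738) or 2 (0.247) or 22.5 kDa replicate 1 (0.0879) or 2 (0.0588) (0.000687 to 0.482 over its alternatives). SREBF1, a transcription factor gene of lipid synthesis, fell by 0.73 but missed the threshold without empty vector replicate 1 (0.206) or 2 (0.202) or 22.5 kDa replicate 1 (0.101) or 2 (0.0734) (0.00129 to 0.615 over its alternatives). That list had camera adjusted p = 0.00314, and adjusted p = 0.489 with an estimated correlation. Of 29 interferon response genes, 5 fell and 0 rose (6 and 0 adjusted over the list alone), with the antigen presentation gene HLA-B at 1293 ± 0.507 and 406 ± 19.9 CPM (log2 fold change -1.67). Camera adjusted p was 0.004, adjusted p = 0.618 with an estimated correlation, and the list missed the threshold without empty vector replicate 1 (0.201) or 22.5 kDa replicate 1 (0.0556) (3.14e-07 to 0.618 over its alternatives).

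Of 38 cell cycle genes, 3 fell and 0 rose with 22.5 kDa FGF2 (3 and 0 adjusted over the list alone): the mitotic kinase gene AURKA (-0.77), its activator TPX2 (-0.75) and the transcription factor gene FOXM1 (-0.93). AURKA missed the threshold without empty vector replicate 1 (0.079) or 2 (0.274) or 22.5 kDa replicate 1 (0.111), TPX2 without empty vector replicate 1 (0.101) or 2 (0.336) or 22.5 kDa replicate 1 (0.0933) or 2 (0.052), and FOXM1 without empty vector replicate 1 (0.0778) or 2 (0.0528) or 22.5 kDa replicate 1 (0.0793). Their adjusted p-values ranged over 0.000702 to 0.527, 0.0011 to 0.579 and 2.15e-05 to 0.234 across their alternatives. Camera adjusted p was 0.0272, adjusted p = 0.618 with an estimated correlation, and the list missed the threshold without empty vector replicate 1 (0.0796) or 2 (0.0818) or 22.5 kDa replicate 1 (0.138) (0.0129 to 0.618 over its alternatives). Of 27 nucleolar and ribosome biogenesis genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone): the RNA polymerase I subunit genes POLR1A (1.20) and POLR1B (1.25) and the ribosomal RNA processing gene NOP56 (0.94). POLR1A missed the threshold without empty vector replicate 1 (0.0641), POLR1B without empty vector replicate 1 (0.0928), and NOP56 without empty vector replicate 1 (0.211) or 22.5 kDa replicate 2 (0.0501) (1.47e-06 to 0.0641, 3.75e-07 to 0.0928 and 5.49e-06 to 0.211 over their alternatives). Camera adjusted p was 0.00675, adjusted p = 0.551 with an estimated correlation, and the list missed the threshold without empty vector replicate 1 (0.0947) (0.00405 to 0.551 over its alternatives). POLR1A and POLR1B lie on chromosome 2, as GREB1 and FN1 do. Its 836 tested genes had a median log2 fold change of 0.59 with 22.5 kDa and 0.35 with 18 kDa FGF2, and the 18 kDa libraries were at 0.16 and 0.48.

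Neither Wnt list passed with 22.5 kDa FGF2. Of 15 Wnt/beta-catenin target genes, 2 rose and 3 fell (2 and 3 adjusted over the list alone, camera adjusted p = 0.877). SOX9 fell by 2.61 and LEF1 was 25.7-fold lower (interval 8.46 to 128). RNF43 rose by 1.08 and KREMEN1 fell by 1.25, but RNF43 missed the threshold without empty vector replicate 2 (0.161) and KREMEN1 without 22.5 kDa replicate 1 (0.0579) (2.45e-06 to 0.161 and 3.98e-07 to 0.0579 over their alternatives). Of 27 Wnt ligands, receptors and modulators, 5 rose and 2 fell (5 and 3 adjusted over the list alone, camera adjusted p = 0.544). The receptor gene FZD4 rose by 1.21, and WLS fell by 5.80. The ligand gene WNT6 rose by 2.67 but missed the threshold without 22.5 kDa replicate 2 (0.0579) (2.68e-10 to 0.0579 over its alternatives).

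The other lists did not pass with 22.5 kDa FGF2 in the camera test. With fry, androgen-regulated genes (adjusted p = 0.00329, 0.00329 to 0.618 over its alternatives) and fibroblast markers (0.0414, 0.0414 to 0.944) passed downward, and interferon (0.332, 3.14e-07 to 0.618), cell cycle (0.126, 0.0129 to 0.618) and nucleolar genes (0.0733, 0.00405 to 0.551) did not pass. Members higher and lower, with the counts adjusted over the list alone and the camera adjusted p in brackets, were 2 and 1 of 16 androgen-regulated genes (2 and 2, 0.544), 4 and 2 of 13 apocrine genes (4 and 3, 0.877), 2 and 4 of 19 progestin-regulated genes (3 and 5, 0.501), 2 and 2 of 21 luminal genes (2 and 2, 0.687) and 4 and 2 of 13 basal genes (4 and 3, 0.687). AZGP1 fell by 3.50, EDN1 rose by 2.52, TRIM29 rose by 3.53 and LAMB3 rose by 2.06. They were 2 and 3 of 13 stem and progenitor genes (2 and 5, 0.165), 1 and 3 of 25 unfolded protein response genes (1 and 3, 0.729), 4 and 2 of 24 hypoxia genes (4 and 2, 0.729), 2 and 0 of 23 apoptosis regulators (2 and 0, 0.729) and 2 and 4 of 18 growth factors and chemokines (2 and 7, 0.165). The pyruvate dehydrogenase kinase gene PDK1 rose by 2.36 and the pro-apoptotic gene BIK rose by 2.28. Fibroblast markers had 0 and 1 of 5 members (1 and 2, 0.544), heat shock genes 0 and 1 of 15 members (0 and 1, 0.687), and histone genes 0 and 0 of 9 members (0 and 0, 0.771) with edgeR. Of the markers too few for a list test, 0 and 1 of 3 endothelial, 0 and 0 of 1 leukocyte and 0 and 2 of 4 adipocyte markers were higher and lower (0 and 1, 0 and 0 and 0 and 2 adjusted over the list alone), with PLIN4 at -2.18. Median, mean and test differed in sign for the Wnt target, apocrine, unfolded protein response, hypoxia and apoptosis lists.

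Across all genes, 1431 passed with 22.5 kDa FGF2, 659 higher and 772 lower, 419 and 598 of them by over 2-fold. GRIK4 was at least 6.01-fold higher, CCL2 rose by 6.51 (SE 0.49), DSCAM rose by 5.88 (SE 0.43) and HCFC2 rose by 4.52 (SE 0.37). SSX2 and SSX2B were 74.5-fold higher (interval 25.2 to 364) and NTN4 26-fold (6.87 to 220). EREG, an EGF receptor ligand gene, had 131 counts in the empty vector and 0 with 22.5 kDa FGF2 (at least 22.5-fold lower). TENM2 was 207-fold lower (interval 36.7 to 8220), RHAG 81.9-fold (22.3 to 682), SLFN11 72.9-fold (19.8 to 608) and ZNF689 66.2-fold (22.3 to 324). The gene DSCAM is on chromosome 21, whose 133 tested genes had a median log2 fold change of 0.55 with 22.5 kDa and -0.04 with 18 kDa FGF2. DSCAM lies in a window of 25 neighbouring tested genes with a median of 0.66, PDK1, GREB1, POLR1B and WNT6 on chromosome 2 in windows of up to 0.91, 0.79, 0.71 and 0.69, and SSX2 and SSX2B on chromosome X in a window of 0.80, beyond what permuted gene orders gave. The count was 775 without empty vector replicate 1, 792 without replicate 2, 797 without 22.5 kDa replicate 1 and 630 without replicate 2. It was 643 against a fold of 1.5, 2535 without both replicate 1 libraries of the FGF2 groups and 2361 after removal of each library's GC trend. The share of higher genes, 46.1%, turned to a majority without 22.5 kDa replicate 1 (447 higher and 350 lower, 56.1%) and without both replicate 1 libraries (1409 and 1126, 55.6%). It was 51.2% without 18 kDa replicate 1, 51.1% with only the groups compared and 51.2% after removal of the GC trend. Of 93 named genes that passed, 51 still passed without any 1 of the 6 libraries.

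The changes against the empty vector overlapped between the isoforms. Of the 13124 genes, 332 passed higher with both isoforms, 398 passed lower with both and 5 passed in opposite directions. Those in the same direction were 62.7% of the 18 kDa genes and 51.0% of the 22.5 kDa genes. Independent lists of these sizes would share 27 higher and 36.9 lower. Across genes, which are not independent replicates, the correlation of log2 fold changes was 0.756, and in 20 simulations of unchanged groups against the same controls it averaged 0.506 (highest 0.529). The covariance was 0.54 against a simulated 0.0745 (highest 0.0811), a difference of 0.466, and 72.6% of genes had the same sign against 66.8%. The simulations gave 0.3 shared genes on average and at most 3. Both comparisons use the same empty vector libraries, which are too few to split, so part of the excess may come from them. The 730 shared genes became 401 without empty vector replicate 1, 412 without replicate 2 and 401 without 22.5 kDa replicate 2.

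The direct comparison asks which genes differ between the nuclear 22.5 kDa and the 18 kDa isoform. TGFB1 was at 6.86 ± 1.92 CPM with 22.5 kDa and 43.0 ± 9.10 CPM with 18 kDa FGF2 (SD, n = 2, log2 fold change -2.66, SE 0.28, adjusted p = 1.18e-06). AREG, an EGF receptor ligand gene, was at 23.0 ± 6.40 against 115 ± 10.6 CPM (-2.31, SE 0.24, adjusted p = 1.18e-06). HCFC2, a transcription regulator gene, was at 71.9 ± 27.1 against 2.49 ± 0.701 CPM (4.85, SE 0.38, adjusted p = 7.98e-09), and ZDHHC4 had 339 counts against 0, at least 60.9-fold higher with 22.5 kDa FGF2. In the empty vector ZDHHC4 had 402 counts, so this difference lies in its absence with 18 kDa FGF2. PGR (0.05, SE 0.31, adjusted p = 0.961), ESR1 (0.68, SE 0.61, adjusted p = 0.702) and FGFR1 (0.15, SE 0.27, adjusted p = 0.866) did not pass, which does not show that they were alike. FGFR2 (0.39, SE 0.56, adjusted p = 0.832), FGFR4 (0.52, SE 0.29, adjusted p = 0.505), CTNNB1 (0.29, SE 0.26, adjusted p = 0.701) and NUDT6 (-0.63, SE 0.73, adjusted p = 0.775) did not pass either.

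Of the gene lists, 0 of 23 passed with camera between the isoforms (1 at an unadjusted p under 0.05, smallest adjusted p = 0.293, growth factors and chemokines), 0 with an estimated correlation (0 unadjusted) and 0 with fry (2 unadjusted). Without 22.5 kDa replicate 1 the growth factor list passed with adjusted p = 0.0446 (0.0446 to 0.876 over its alternatives). Single members passed, and in brackets follow members higher and lower over all genes and then adjusted over the list alone. Here rose and fell mean higher and lower with 22.5 kDa than with 18 kDa FGF2, not a change from the empty vector. FGFR3, ELF5 and FKBP5 were lower and SDC1 higher with 18 kDa FGF2 than in the empty vector, so their differences lie at least partly in the 18 kDa group. FZD4 and WNT6 were higher with 22.5 kDa FGF2 than in the empty vector. FZD4 rose by 1.53 and WNT6 rose by 2.99 among Wnt ligands and receptors (2 and 0 of 27, 2 and 0), and FGFR3 rose by 1.23 and SDC1 fell by 1.00 among FGF ligands and receptors (1 and 1 of 15, 1 and 2). The secretory gene AGR2 rose by 2.43 and ELF5 rose by 1.08 among luminal genes (2 and 0 of 21, 2 and 0), and FKBP5 rose by 1.00 among androgen-regulated (1 and 0 of 16, 1 and 0) and, with ELF5, progestin-regulated genes (2 and 0 of 19, 2 and 0). AREG fell among estrogen-regulated genes (0 and 1 of 26, 0 and 1) and growth factors (0 and 1 of 18, 1 and 5), and TGFB1 among transition genes (0 and 1 of 10, 0 and 1). KYNU fell by 2.28 among apocrine genes (0 and 1 of 13, 1 and 2), CD24 fell by 1.00 among stem genes (0 and 1 of 13, 0 and 1), HLA-B fell by 1.27 among interferon genes (0 and 1 of 29, 0 and 2) and SREBF1 fell by 0.88 among cholesterol genes (0 and 1 of 27, 0 and 1). In the other lists 0 members passed over all genes with edgeR, and adjusted over the list alone fibroblast markers had 2 and 0, heat shock genes 1 and 1 and endothelial markers 0 and 2 higher and lower. Without 1 library the threshold was missed by FZD4 (without 22.5 kDa replicate 2 (0.0564)), WNT6 (without 22.5 kDa replicate 2 (0.135)), FGFR3 (without 18 kDa replicate 1 (0.0552) or 22.5 kDa replicate 1 (0.0904) or 2 (0.221)), SDC1 (without 18 kDa replicate 1 (0.204) or 22.5 kDa replicate 1 (0.259) or 2 (0.0912)) and AGR2 (without 22.5 kDa replicate 2 (0.0564)). It was missed by ELF5 (without 18 kDa replicate 1 (0.221) or 22.5 kDa replicate 1 (0.484) or 2 (0.101)), FKBP5 (without 18 kDa replicate 1 (0.204) or 22.5 kDa replicate 1 (0.256) or 2 (0.108)), KYNU (without 22.5 kDa replicate 1 (0.234) or 2 (0.0925)), CD24 (without 22.5 kDa replicate 2 (0.249)), HLA-B (without 22.5 kDa replicate 2 (0.0564)) and SREBF1 (without empty vector replicate 1 (0.0528) or 2 (0.0556), 18 kDa replicate 1 (0.241) or 22.5 kDa replicate 1 (0.2) or 2 (0.123)). Median, mean and test differed in sign for the FGF ligand, androgen, apocrine, estrogen, luminal, basal, stem and heat shock lists.

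In all, 207 genes differed between the isoforms, 148 higher with 22.5 kDa FGF2 and 59 lower, 128 and 51 of them by over 2-fold. Of 32 named genes that passed, 10 still passed without any 1 of the 6 libraries: ZDHHC4, CREB3L1, HCFC2, ZNF853, GPNMB, ZNF689, TENM2, CSTF2T, TGFB1 and AREG. The count was 37 without 22.5 kDa replicate 2, 66 without 22.5 kDa replicate 1, 135 without 18 kDa replicate 1 and 733 without 18 kDa replicate 2. It was 109 with upper-quartile size factors, 445 without a low-count filter, 327 with the likelihood ratio test and 78 against a fold of 1.5. It was 354 without both replicate 1 libraries, and 320 after removal of each library's GC trend, which kept 179 of the 207. Between the isoforms, the 133 tested genes of chromosome 21 had a median log2 fold change of 0.64. The 836 of chromosome 2, where WNT6, KYNU, IRS1 and LONRF2 lie, had 0.23, and 0.08 after removal of the GC trend. AGR2, GPNMB, ZDHHC4 and ZNF853 on chromosome 7 lie in windows of 25 neighbouring tested genes with medians of up to 0.84, and IRS1 in windows of up to 0.73, beyond what permuted gene orders gave.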

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

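The comparison with abundant luminal genes, the limits of 5 and 0.5 CPM for genes on and off, the fit without both replicate 1 libraries and the removal of the GC trend were chosen only after the results were seen. The calculations on copies, neighbouring genes and estrogen-regulated genes were also redone to follow their written predictions after first values had been seen, and the verdicts on copies and on copy number changed with that.

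A direct test found 207 genes that differed between 22.5 kDa and 18 kDa FGF2, the reason why each of the following is listed. ZDHHC4 was at least 60.9-fold, MBP at least 4.7-fold and PTGER3 at least 2.42-fold higher with 22.5 kDa FGF2. They had 402, 34 and 44 counts in the empty vector, 0 with 18 kDa and 339, 26 and 15 with 22.5 kDa FGF2. LONRF2 was at 12.57 CPM in the empty vector, 0.48 with 18 kDa and 6.33 with 22.5 kDa FGF2. These differences thus lie in low levels with 18 kDa FGF2. APOL4 instead had 1 count in the empty vector, 2 with 18 kDa and 66 with 22.5 kDa FGF2. By ratio of counts CREB3L1 was 58.9-fold (interval 19.8 to 289), APOL4 34.9-fold (9.29 to 294) and IRS1 16.2-fold higher (5.22 to 81.6). ZNF689 was 121-fold (41.1 to 589), TENM2 77.5-fold (13.5 to 3100), FBXL7 13.5-fold (4.34 to 68.3) and SLFN11 12.8-fold lower (3.21 to 111). Log2 fold changes were 4.85 for HCFC2, 4.78 for ZNF853, 4.42 for GPNMB and 3.65 for LONRF2. They were -4.19 for ACTL10, -3.77 for CSTF2T, -3.49 for RMRP, -2.81 for TRO, -2.66 for TGFB1 and -2.66 for CDH8. Among list members they were 1.23 for FGFR3, 2.43 for AGR2, 1.08 for ELF5, 0.999 for FKBP5, 2.99 for WNT6 and 1.53 for FZD4. They were -1 for CD24, -1.27 for HLA-B, -2.31 for AREG, -0.997 for SDC1, -0.88 for SREBF1 and -2.28 for KYNU. Of these 32 genes, 21 missed the threshold without 22.5 kDa replicate 2, 14 without 22.5 kDa replicate 1, 7 without 18 kDa replicate 1, 2 without 18 kDa replicate 2 and 1 without each empty vector library. Among them were MBP (without 22.5 kDa replicate 2 (0.124)), PTGER3 (without 18 kDa replicate 1 (0.184) or 2 (0.0544) or 22.5 kDa replicate 1 (0.667) or 2 (0.101)), APOL4 (without 22.5 kDa replicate 2 (0.0762)), IRS1 (without 22.5 kDa replicate 1 (0.104) or 2 (0.108)), LONRF2 (without 22.5 kDa replicate 1 (0.0692)) and ACTL10 (without 22.5 kDa replicate 2 (0.0514)), with adjusted p in brackets. So were FBXL7 (without 22.5 kDa replicate 1 (0.264) or 2 (0.0564)), SLFN11 (without 18 kDa replicate 2 (0.0884) or 22.5 kDa replicate 1 (0.357) or 2 (0.202)), RMRP (without 22.5 kDa replicate 1 (0.153) or 2 (0.199)), TRO (without 18 kDa replicate 1 (0.244) or 22.5 kDa replicate 1 (0.295) or 2 (0.196)) and CDH8 (without 22.5 kDa replicate 1 (0.462) or 2 (0.0651)). The list members that missed it were FGFR3 (without 18 kDa replicate 1 (0.0552) or 22.5 kDa replicate 1 (0.0904) or 2 (0.221)), AGR2 (without 22.5 kDa replicate 2 (0.0564)), ELF5 (without 18 kDa replicate 1 (0.221) or 22.5 kDa replicate 1 (0.484) or 2 (0.101)), FKBP5 (without 18 kDa replicate 1 (0.204) or 22.5 kDa replicate 1 (0.256) or 2 (0.108)), WNT6 (without 22.5 kDa replicate 2 (0.135)) and FZD4 (without 22.5 kDa replicate 2 (0.0564)). They were also CD24 (without 22.5 kDa replicate 2 (0.249)), HLA-B (without 22.5 kDa replicate 2 (0.0564)), SDC1 (without 18 kDa replicate 1 (0.204) or 22.5 kDa replicate 1 (0.259) or 2 (0.0912)), SREBF1 (without empty vector replicate 1 (0.0528) or 2 (0.0556), 18 kDa replicate 1 (0.241) or 22.5 kDa replicate 1 (0.2) or 2 (0.123)) and KYNU (without 22.5 kDa replicate 1 (0.234) or 2 (0.0925)).

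Replicates lay far apart along component 2. The replicate 1 minus replicate 2 difference followed GC content across genes with a Spearman rho of 0.534 in the 18 kDa group and -0.602 in the 22.5 kDa group (-0.256 in the empty vector), so a GC bias between libraries may account for this spread. Thinning to equal totals left 101% of the distance between the replicate 1 libraries of the FGF2 groups (90.7 before, 91.3 after), so library size does not account for that distance. The distance between replicates of a group was not computed after thinning, so library size is not excluded for it. Transcript length was not formally excluded, with a rho of 0.00621 and 0.103, far under the 0.3 that it needed but in 1 group just over the bound of 0.1 set to exclude it. After removal of the GC trend 320 genes differed between the isoforms, 179 of the 207 among them, and no biological explanation was tested.

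Some genes were on in 1 group (at least 5 CPM) and off in another (under 0.5 CPM), 53 genes over the 3 comparisons. Reads shared with near-identical copies stay open. Of these genes 3.77% had a gene of identical counts (SSX2 and SSX2B). With relatives of the same symbol stem and direction among them it was 11.3% (also SLFN11, SLFN13, C5AR1 and C5AR2). With relatives among all genes that passed it was 35.8%, between the bounds set for and against this cause. A symbol stem does not measure likeness of sequence (ZNF689 and FBXL7 also had such relatives). The shares with relatives thus cannot decide on shared reads. Loss or gain of chromosome segments stays open. The 152 values of neighbouring tested genes had a median signed log2 fold change of 0.197, but with an SD of 1.77 and with 18.4% of them at 1 or more. A gene can occur more than once among these values. Some neighbours were on and off genes themselves, such as RHAG and TFAP2B, or SSX2 and SSX2B. Clonal differences between the lines, and an effect of FGF2, stay open and were not tested.

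ESR1 and 12 of 26 measured estrogen-regulated genes, PGR among them, were lower in both FGF2 groups, while the call of the whole list was lost with an estimated correlation (adjusted p = 0.602 with 18 kDa and 0.489 with 22.5 kDa FGF2, with ranges of 4.65e-09 to 0.602 and 3.21e-09 to 0.489 over its alternatives). A single unusual empty vector library does not account for this, since 10 of 12 members lower in both comparisons (83.3%) were still so without either library, all except SIAH2 and CELSR2. After removal of the trend on transcript length and GC, the members' median log2 fold change was -3.74 with 18 kDa FGF2 (-3.65 before). With 22.5 kDa FGF2 it was -3.12 (-3.24 before, or -3.10 with genes without counts at their bound). The trend held only 0.0149 and 0.0122 of the variance of fold changes, so its removal could hardly have moved these medians. These 12 members were picked as lower, and the medians over all 26 were -0.91 and -0.894 before removal. Cells of a type that is not luminal would lower the abundant luminal genes KRT8, KRT18, KRT19, CDH1, EPCAM, GATA3 and FOXA1 as well. The median of these luminal genes was 0.0604 with 18 kDa (SD 0.406) and -0.27 with 22.5 kDa FGF2 (SD 0.464). These values do not speak to replacement by other luminal cells. That FGF2 itself lowers these genes is a hypothesis, and a difference between the lines that arose apart from FGF2 was not tested and remains open. Counts per gene would not tell an introduced copy of PGR from the cell's own gene, so the fall of PGR need not reflect estrogen regulation.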

How the results depend on the processing

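Removal of the GC trend, the fit without both replicate 1 libraries of the FGF2 groups and the crossed block were chosen only after the results were seen. Of 5425 values for 286 gene results under the alternatives, 5050 kept their direction and side of the threshold, 346 fell short of it, 29 newly passed and 0 turned. For 69 list results with 690 values these were 641, 34, 14 and 1. The 1 that turned was hypoxia and glycolysis genes with 18 kDa FGF2, which passed in the other direction without empty vector replicate 1 (adjusted p = 0.0426, range 0.0224 to 0.97), and the cause was not tested. The 1165 genes for 18 kDa FGF2 became 496 against a fold of 1.5, 1915 without both replicate 1 libraries and 1813 without the GC trend. The 1431 for 22.5 kDa FGF2 became 643, 2535 and 2361, and the 207 between the isoforms 78, 354 and 320. The last count also became 109 with upper-quartile size factors, 445 without a low-count filter and 327 with the likelihood ratio test. The test against a fold asks for more, and for the others the cause was not tested. Leaving out 1 library gave 617 to 1440, 630 to 1964 and 37 to 733 genes, 401 to 731 shared genes, and 2 to 7, 5 to 8 and 0 to 1 lists. For 18 kDa FGF2 the lowest counts came without empty vector replicate 1 (617) or 2 (665), and the share of higher genes was then 35.2% and 35.3%. For 22.5 kDa FGF2 they were 775 and 792 without empty vector replicate 1 and 2, and 797 and 630 without 22.5 kDa replicate 1 and 2. Between the isoforms the counts were 135 and 733 without 18 kDa replicate 1 and 2, and 66 and 37 without 22.5 kDa replicate 1 and 2. The shared genes were 401 and 412 without empty vector replicate 1 and 2, and 401 without 22.5 kDa replicate 2. The number of lists was 2 for 18 kDa FGF2 without 18 kDa replicate 2, 5 for 22.5 kDa FGF2 without empty vector replicate 1 or 22.5 kDa replicate 1, and 1 between the isoforms without 22.5 kDa replicate 1. The lists became 0 and 0 with an estimated correlation, and the estrogen list ranged over 4.65e-09 to 0.602 and 3.21e-09 to 0.489. Among lists that lost their call, the estimate lay above the preset 0.01 for interferon genes (0.322). It lay below it for epithelial-mesenchymal transition genes with 22.5 kDa FGF2 (-0.095), whose unadjusted camera p still rose from 0.00176 to 0.0469. A higher correlation thus cannot account for that loss. The estimated setting takes its p-values from 3 residual degrees of freedom, which raises them. How much of the other losses came from this was not tested.

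The replicate numbers were not taken to pair the samples, since the labels do not say whether equal numbers share a culture or day. Same-numbered deviations correlated at -0.271 between empty vector and 18 kDa, 0.387 between empty vector and 22.5 kDa, and -0.413 between 18 kDa and 22.5 kDa libraries. The replicate differences also followed GC content with differing signs, so these correlations cannot tell whether the samples were paired. With the replicate number as a block 1210, 1523 and 337 genes passed, with 748 shared, and with crossed numbers 2434, 2910 and 1208. The camera test with the block gave 4 lists for 18 kDa FGF2 (5 without it), 8 for 22.5 kDa FGF2 and 0 between the isoforms. Other settings kept within 1.5 times: DESeq2 gave 970, 1184 and 212 genes, limma-voom 1130, 1395 and 205, and RLE factors 1241, 1552 and 290. The filter of at least 1 CPM kept 13980 genes and gave 1240, 1535 and 235. With totals of 5317687 to 6817324 counts and 2 libraries per group, most genes changed 2-fold in simulated counts were missed (31% to 42.4% recovered), so a gene that did not pass may still differ by that much. Neither depth nor the number of libraries was varied, so the cause was not tested.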

Other observations

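The tests of chromosome medians and windows were chosen only after the result was seen, and the correlation of neighbouring genes was not.

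Other single list members changed too. P-cadherin CDH3 rose by 1.63 with 18 kDa and by 1.35 with 22.5 kDa FGF2 on the log2 scale, and the pro-apoptotic gene BIK rose by 2.33 and by 2.28. The stem cell transcription factor gene KLF4 fell by 1.88 with 18 kDa FGF2. With 22.5 kDa FGF2 the clock gene PER1 fell by 1.52, the metallothionein gene MT2A fell by 1.24 and the smooth muscle gene TAGLN fell by 1.37, while CRAT, a carnitine acetyltransferase gene, rose by 1.30. With 18 kDa FGF2 the chemokine gene CCL28 rose by 2.27.

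Fold changes of neighbouring genes were weakly correlated, beyond what permuted gene orders gave. Over 13050 adjacent pairs the correlation across genes was 0.226 between the isoforms, 0.207 with 18 kDa and 0.229 with 22.5 kDa FGF2 against the empty vector, and the highest of 100 permutations of gene order was 0.0199, 0.0213 and 0.0179. Of 2515 windows of 25 genes, 98, 101 and 84 lay beyond the permuted range. With 22.5 kDa FGF2 their medians reached 1.68 on chromosome X and -1.39 on chromosome 5, at protocadherin genes, and between the isoforms 0.84 and -0.57 on chromosome 7. Chromosome 2 (836 genes) had a median log2 fold change of 0.35 with 18 kDa and 0.59 with 22.5 kDa FGF2, beyond permuted ranges of -0.18 to 0.05 and -0.12 to 0.12. After removal of the GC trend these were 0.43 and 0.54. Its 18 kDa libraries were at 0.16 and 0.48 and its 22.5 kDa libraries at 0.645 and 0.44. A fixed difference in copy number alone would give replicates alike values. Replicates of both groups also differed along GC content (rho 0.534 and -0.602), so the gap may be technical and does not decide on copy number. Chromosome X (413 genes) had 0.14 and 0.18, beyond the same ranges, with 0.09 and 0.23 in the 18 kDa and 0.28 and 0.14 in the 22.5 kDa libraries, and 0.175 and 0.14 after removal of the GC trend. With 18 kDa FGF2 chromosomes 20 (0.13) and 22 (0.06) also lay above and 5 (-0.20), 6 (-0.19) and 18 (-0.19) below the range, and with 22.5 kDa FGF2 chromosome 19 (-0.20) below it. After removal of the GC trend these were 0.12, 0.01, -0.13, -0.09, -0.07 and -0.155. Between the isoforms chromosomes 1 (0.16), 2 (0.23), 4 (0.18), 13 (0.17) and 21 (0.64) lay above and 16 (-0.14), 19 (-0.18) and 22 (-0.125) below a range of -0.08 to 0.15. After removal of the GC trend chromosome 21 had 0.555 and chromosome 1 had 0.13, and chromosomes 2, 4, 13, 16, 19 and 22 had 0.08, 0.02, 0.00, -0.06, -0.07 and -0.05, each closer to 0. Chromosome 21 (133 genes) had 0.55 with 22.5 kDa and -0.04 with 18 kDa FGF2, and each 22.5 kDa library showed it (0.60 and 0.54) against 0.01 and 0.02 in the 18 kDa libraries. Windows on chromosomes 1 (16 above) and 7 (14 above, 13 below) between the isoforms also lay beyond the range. So did 10 on chromosome 20 with 18 kDa FGF2. On chromosome X 25 of 78 windows with 18 kDa and 20 of 78 with 22.5 kDa FGF2 lay above it. All of these X windows lie between PLCXD1 and KDM5C, so the X medians do not stand for the whole chromosome. For chromosome 2 and this part of X in both comparisons with the empty vector, and 21 with 22.5 kDa FGF2 (0.56 after removal of the GC trend), a candidate explanation is that copy number differs between the lines, which may have arisen in selection of the cells rather than from FGF2. Clusters of genes regulated together would give a like correlation, and copy number was not measured. Genes with identical counts in every library (UGT1A4, UGT1A5, UGT1A7 and UGT1A8, and SSX2 and SSX2B) were not left out. Reads shared between neighbours may thus add to the correlation and the window medians, which was not tested.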
